A study of Homo sapiens with 6 samples.

How the data were processed

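RNA sequencing had been run on 6 libraries of A549 cells, an established human lung adenocarcinoma line, infected with lentiviruses that expressed a control or a shCBX8 short hairpin RNA to obtain stable lines. Total RNA had been taken with Trizol and libraries made with standard Illumina protocols. The sample titles give 3 groups of 2 libraries, control, shCBX8-1 and shCBX8-2. Neither the meaning of the first number in the shCBX8 titles nor whether the 2 libraries of a group came from separate cultures is stated. The p-values therefore measure the spread between these samples, which may be technical.

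The deposited table holds expected counts, that is estimated read counts per RefSeq transcript, not scaled to a common total. The authors' processing notes name HISAT2 2.2.1, StringTie 2.2.1 and DESeq2 1.34.0 and the genome build hg38, without saying which tool did what. The annotation and the step that made the counts are not given in the sources used here. All values were whole numbers already, so rounding changed nothing. Counts of the transcripts of a gene were summed per gene, as fixed beforehand.

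Of 84787 transcripts listed, 83963 were matched to a gene by the RefSeq table of GRCh38.p14 and 355 by GENCODE tables, 99.45% in all. The other 469 had no match and were kept as entries of their own. A further label on 12094 of the entries marks an accession that is repeated, as for copies at other loci, and these held 2.89 to 3.17% of the counts of a library. Summing gave 28452 genes, with the unmatched entries counted among them. Total estimated counts were 64197784 to 67169537 per library. At that depth a gene without counts in both libraries of a group was placed below a floor of 3 counts over the group, which covers counting error only, and folds against such a group are given as lower bounds.

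Genes were tested in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr (minimum count 10, minimum total 15) kept 17115 genes, libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with 3 groups was fitted to all 6 libraries, with 3 residual degrees of freedom and 1 shared estimate of the spread. The common dispersion was 0.0369, a biological coefficient of variation of 19.2%. There were 4 contrasts: the mean of both knockdown groups minus control, each knockdown group minus control, and shCBX8-2 minus shCBX8-1. P-values were two-sided and were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05 and no minimum fold. Standard errors of log2 fold changes were derived from the F statistic. Levels are counts scaled by TMM to a common library total (CPM).

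Before the data were examined, the comparisons, tests, 30 gene lists and the rule for named genes were fixed. The rule takes CBX8, CDKN2C and SCEL. For knockdown against control it adds the 12 highest and 12 lowest fold changes among genes that passed in that contrast and in both groups with the same sign. For each other contrast it adds the 5 highest and 5 lowest that passed, and for each list up to 4 members with the smallest p in knockdown against control. A mean of at least 1 CPM was required for the genes taken by fold change. Genes outside the rule are named as chosen after their values were seen.

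The lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, with at least 5 measured members, and adjusted over the 29 lists that could be tested. The list of mitochondrially encoded genes, 13 in number, had 0 members in the table and was not analysed here. The camera test compares a list with the other genes. It was repeated with a correlation estimated per list, and fry was run beside it, which tests whether a list's genes move, on balance, one way and compares them with no other genes. List p-values are those of camera at the preset correlation unless another is named. Members at 0 in a group occurred in 8 lists, and placing them at their bound moved no list median by more than 0.0089.

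The pipeline was tested on simulated data with 16692 genes. For knockdown against control, edgeR recovered 34.3% of genes changed 1.5-fold, 73.1% at 2-fold and 97% at 4-fold. Of its 154 calls, 18 were unchanged genes, a share above the nominal 5%. DESeq2 1.42.0 made 214 calls there, of which 59 were unchanged genes. In the simulation a gene had the same spread in every group and both knockdown groups changed alike. In the real libraries the spread was wider in shCBX8-2 and the knockdown groups differed, so these shares need not hold there. A list shifted by -0.5 log2 was found, with adjusted p = 6.4e-112 and adjusted p = 0.00268 with an estimated correlation, and 0 other lists were called by camera with either.

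Alternatives fixed beforehand were DESeq2 size factors, the DESeq2 Wald test, a minimum of 2-fold, no filter on low counts, each library left out in turn, replicate number as a block, the 4 knockdown libraries as 1 group, a fit of only the libraries compared, and transcripts tested as deposited. Added after seeing the data were leaving out repeated accessions, a robust fit, and removal of each library's trend on abundance or on GC content and transcript length by loess. GC content and length were known for 16233 of the 17115 genes, or 94.8%. No group had 3 libraries, so other splits of the samples were not counted. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 made the remaining tables and plots.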

Results

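Gene expression was measured by RNA sequencing in A549 lung adenocarcinoma cells that stably carried a control or a shCBX8 hairpin. Each of the 3 groups, control, shCBX8-1 and shCBX8-2, had 2 libraries. Total estimated counts were 64751043 and 64822441 in control, 64197784 and 65515050 in shCBX8-1, and 67169537 and 64317603 in shCBX8-2. Between 17985 and 18788 genes had a count above 0 per library. KRT8, a keratin of simple epithelia, was the most abundant gene in all 6 libraries, with 1.19 to 1.62% of the counts. The libraries of a group differed by a median of 0.129 log2 per gene in control, 0.128 in shCBX8-1 and 0.240 in shCBX8-2. In the shCBX8-2 libraries the deviation of genes from the mean of all libraries followed GC content in opposite directions. The Spearman correlation across 13265 genes, which are not independent replicates, was 0.422 in replicate 1 and -0.306 in replicate 2.

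The series title names CDKN2C and SCEL as genes repressed by CBX8, a chromobox subunit of Polycomb repressive complex 1, so their levels and that of CBX8 were compared first. CBX8 (gene 57332, GRCh38.p14 chromosome 17, 79792132 to 79797077) averaged 25.4 ± 1.15 CPM in control (SD, n = 2), 7.75 ± 0.0623 CPM in shCBX8-1 and 15.8 ± 2.82 CPM in shCBX8-2, or 30.4% and 61.9% of the control mean. CDKN2C (gene 1031, chromosome 1, 50960745 to 50974634), an inhibitor of cyclin-dependent kinases of the INK4 family, averaged 20.9 ± 0.632 CPM in control, 38.0 ± 0.826 CPM in shCBX8-1 and 44.2 ± 2.29 CPM in shCBX8-2 (SD, n = 2). SCEL (gene 8796, chromosome 13, 77535706 to 77645263), which codes for sciellin, a precursor of the cornified envelope, averaged 7.35 ± 0.558, 17.7 ± 3.08 and 24.8 ± 2.31 CPM (SD, n = 2). Each of the 4 knockdown libraries had less CBX8 than either control, 7.70 to 17.7 CPM against 24.6 and 26.3 CPM.

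Against control, the mean log2 fold change of both knockdown groups was -1.20 ± 0.13 for CBX8 (SE, adjusted p = 0.00755), 0.97 ± 0.09 for CDKN2C (adjusted p = 0.00597) and 1.51 ± 0.15 for SCEL (adjusted p = 0.0068). CBX8 fell by 1.72 ± 0.16 in shCBX8-1 (adjusted p = 0.00708) and fell by 0.69 ± 0.15 in shCBX8-2 (adjusted p = 0.0297), and these differed (1.02 ± 0.15, adjusted p = 0.0115). CDKN2C rose by 0.86 ± 0.10 and 1.08 ± 0.10 (adjusted p = 0.0144 and 0.00276), and SCEL by 1.27 ± 0.16 and 1.76 ± 0.17 (adjusted p = 0.0205 and 0.00299). The test of shCBX8-2 against shCBX8-1 gave adjusted p = 0.218 for CDKN2C and 0.11 for SCEL. All 3 genes kept their direction without any 1 library. In knockdown against control the calls ended without control 1, control 2, shCBX8-1 replicate 1 or shCBX8-1 replicate 2, with adjusted p of 0.112, 0.139, 0.0642 and 0.0669 for CBX8, 0.103, 0.123, 0.056 and 0.0625 for CDKN2C, and 0.1225, 0.139, 0.056 and 0.0627 for SCEL. The shCBX8-1 calls of all 3 genes ended without the same libraries, with adjusted p up to 0.145 for CBX8, 0.208 for CDKN2C and 0.224 for SCEL. In shCBX8-2 those of CBX8 ended as well (up to 0.17), while that of CDKN2C ended without control 2 (0.0523) and that of SCEL without control 1 (0.056) or control 2 (0.0583). The CBX8 call in shCBX8-2 also ended with the abundance trend removed (0.0643) or with only the libraries compared (0.0681), and its calls against control ended with transcripts tested as deposited (0.26 in knockdown, 0.322 in shCBX8-1 and 0.384 in shCBX8-2). With the 4 knockdown libraries fitted as 1 group the knockdown calls of CBX8 (0.252) and SCEL (0.0876) ended, while CDKN2C passed (0.0481).

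**Figure D1:**
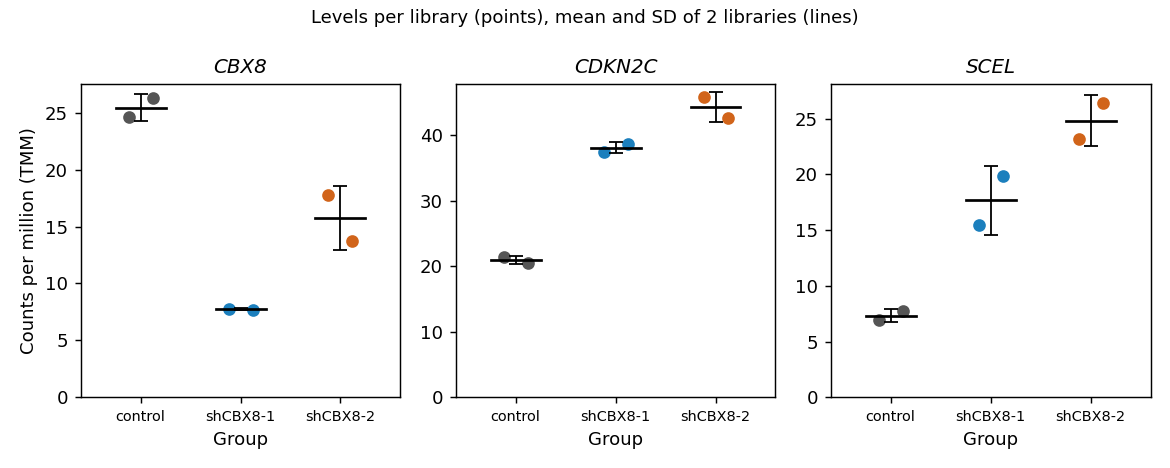
Levels of CBX8, CDKN2C and SCEL in CPM, with a point per library and the mean and SD of the 2 libraries of each group. CBX8 lies between 7.70 and 17.7 CPM in the 4 knockdown libraries, below both controls, while CDKN2C and SCEL lie above both.

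The first comparison asked what differed between CBX8 knockdown and control. Among genes changed in both knockdown groups, H19, an imprinted long non-coding RNA, rose from 10.7 ± 0.79 CPM in control to 48.2 ± 3.42 in shCBX8-1 and 177 ± 0.458 in shCBX8-2 (SD, n = 2), with a mean log2 fold change of 3.11 ± 0.09 (SE, adjusted p = 0.000145). ANPEP, which codes for aminopeptidase N, rose by 3.37 ± 0.25 (adjusted p = 0.00296), and OLFML3, a secreted glycoprotein, by 2.99 ± 0.20 (adjusted p = 0.00285). Further up were the membrane mucin MUC16, at 2.73 ± 0.17 (adjusted p = 0.00285), and the cyclin CCNA1, at 2.29 ± 0.21 (adjusted p = 0.00597). TM4SF20, a membrane protein with several spans, fell from 14.9 ± 0.243 CPM to 2.65 ± 0.281 and 1.27 ± 0.131 CPM (SD, n = 2), with a log2 fold change of -3.02 ± 0.14 (SE, adjusted p = 0.00119). The tetraspanin gene TSPAN18 changed by -2.29 ± 0.29 (adjusted p = 0.0109) and SLC7A7, a subunit of a cationic amino acid transporter, by -2.16 ± 0.17 (adjusted p = 0.00368). The tight-junction gene CLDN2 changed by -2.12 ± 0.14 (adjusted p = 0.00285) and FBN2, which codes for a fibrillin, by -1.95 ± 0.19 (adjusted p = 0.00647). The other genes taken by the rule were FAM156A, FXYD3, EDAR, DOK7, MEGF6 and SUSD2, which rose by 1.51 to 4.73. Lower were NFATC4, KRT20, TCIM, ADM2, BDKRB2, RBFOX3 and KLRG1, at -2.09 to -1.67. H19, FAM156A, NFATC4 and KRT20 include repeated accessions, and without these NFATC4 did not pass (adjusted p = 0.406). FAM156A shares sequence with FAM156B, and their sum was 62.2, 64.8 and 63.6 CPM in control, shCBX8-1 and shCBX8-2. The rise of FAM156A alone is therefore uncertain.

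Of 17115 genes tested, 567 rose and 595 fell in knockdown against control, 1162 in all, and 261 of these changed at least 2-fold, 55 up and 206 down. The count was 1 without control 1, 1 without control 2, 29 without shCBX8-1 replicate 1 and 16 without shCBX8-1 replicate 2, against 3244 and 4467 without shCBX8-2 replicate 1 or 2. In the same order 120, 122, 103 and 110 of the 139 values of genes named here by the rule no longer passed, whereas all passed without either shCBX8-2 library. H19 passed without any 1 library. With the 4 knockdown libraries as 1 group, where the difference between the groups counts as spread, 27 genes passed, and 92 of 104 values of genes named for this comparison no longer passed, H19 (adjusted p = 0.136) among them.

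**Figure D2:**
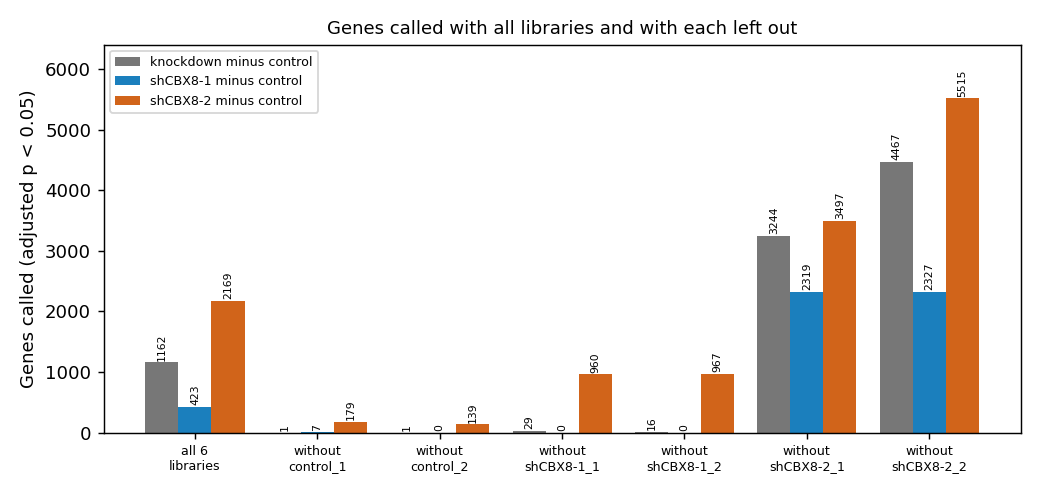
Number of genes past an adjusted p of 0.05 for knockdown, shCBX8-1 and shCBX8-2 against control, with all 6 libraries and with each left out. Bars are lower without a control or shCBX8-1 library and higher without a shCBX8-2 library, as in 1 and 4467 for knockdown against control.

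Genes of cell division were higher in knockdown against control. The list median was 0.42 for G2 and mitosis (adjusted p = 6.16e-34, and adjusted p = 0.0407 with an estimated correlation) and 0.34 for S phase (adjusted p = 3.06e-20, and adjusted p = 0.196 with an estimated correlation). In shCBX8-1 alone neither passed with an estimated correlation (adjusted p = 0.121 and 0.326). Of 62 genes of G2 and mitosis, 34 rose and 28 did not pass, and 49 rose adjusted over the list alone. They included MKI67, a proliferation marker (0.62 ± 0.06, adjusted p = 0.00597), KIF20A, a mitotic kinesin (0.70 ± 0.07, adjusted p = 0.00613), the tubulin gene TUBB4B (0.75 ± 0.08, adjusted p = 0.0068) and AURKB, a kinase of chromosome segregation (0.60 ± 0.07, adjusted p = 0.00923). Of 60 S phase genes, 19 rose and 41 did not pass, and 44 rose adjusted over the list alone, with the replication genes FEN1 (0.55 ± 0.06), MCM7 (0.45 ± 0.06) and MCM4 (0.43 ± 0.06) and the ribonucleotide reductase gene RRM2 (0.54 ± 0.07) among them. RRM2 was called in shCBX8-2 (1.27 ± 0.08) and stood at -0.18 ± 0.07 in shCBX8-1 (adjusted p = 0.27). Of 37 genes of ribosome biogenesis and MYC targets, 4 rose, namely DKC1, NOP56, TCOF1 and PA2G4, all of nucleolar or growth function. Of these 37, 8 rose adjusted over the list alone, and the list median was 0.16 (adjusted p = 4.68e-05, and adjusted p = 0.392 with an estimated correlation).

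Inflammatory cytokines and NF-kB targets were lower, with a list median of -0.43 (adjusted p = 9.23e-05, and adjusted p = 0.196 with an estimated correlation). Of 44 measured, 11 fell, 1 rose and 32 did not pass, and 14 fell and 2 rose adjusted over the list alone. CXCL1, a neutrophil-attracting chemokine, changed by -0.73 ± 0.10 (adjusted p = 0.0122), the kinase gene MAP3K8 by -0.78 ± 0.09 (adjusted p = 0.00947) and the early-response gene IER3 by -0.48 ± 0.07 (adjusted p = 0.0177), while SDC4, a cell-surface proteoglycan, rose by 0.82 ± 0.09 (adjusted p = 0.0083). Cornified envelope and squamous differentiation genes were higher, with a median of 0.58 (adjusted p = 0.000107, and adjusted p = 0.196 with an estimated correlation). Of 24 measured, 4 rose, the keratins KRT15 (1.30 ± 0.12), KRT16 (1.55 ± 0.28) and KRT4 (0.78 ± 0.15) and SCEL, and 7 rose adjusted over the list alone. Of 5 CDK inhibitors CDKN2C rose, and 3 rose adjusted over the list alone. The others were CDKN1B (0.50 ± 0.17) and CDKN2D (0.55 ± 0.16), both named after their values were seen. That list had a median of 0.50 and a mean of 0.07 and was not called (adjusted p = 0.0538, and adjusted p = 0.392 with an estimated correlation). It passed without shCBX8-2 replicate 1 (0.0219) or 2 (0.0166), with the replicate block (0.047), without repeated accessions (0.049) and with the abundance trend removed (0.0424). SCEL and CDKN2C are named by the series title, so their membership is not independent evidence for either list.

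The remaining lists were not called in knockdown against control with all libraries, though some members changed. Of 81 named list members that passed, 34 passed in both groups in the same direction and 1 in opposite directions, 36 passed in shCBX8-2 alone and 10 in shCBX8-1 alone. Among 34 Polycomb repressive complex subunits, EZH2, the histone methyltransferase (0.62 ± 0.08), PHF19 (0.63 ± 0.08) and CBX2 (0.38 ± 0.09, but 0.09 in shCBX8-1) rose and BMI1 fell (-1.13 ± 0.19), likewise 3 and 1 adjusted over the list alone (list adjusted p = 0.44). HOXB13 fell (-0.61 ± 0.11) of 28 HOX cluster genes, and 1 fell adjusted over the list alone (list 0.751). Of 55 developmental transcription factors marked by Polycomb, 2 rose, ZIC2 (0.84 ± 0.10) and KLF4 (0.61 ± 0.10, but 0.16 in shCBX8-1), and 4 fell, with GATA3 (-1.04 ± 0.16) and SOX2 (-1.36 ± 0.22, but 0.18 in shCBX8-1, adjusted p = 0.79) among them, against 2 and 6 adjusted over the list alone (list 0.179). Of 37 p53 target genes 3 fell, GDF15 (-0.65 ± 0.07), GADD45A (-0.41 ± 0.07) and TP53I3 (-0.34 ± 0.07), also 3 adjusted over the list alone (list 0.1). In shCBX8-1 these stood at -0.12, -0.07 and -0.14 and did not pass. Of 44 genes of epithelial adhesion and identity 6 rose, with the integrin gene ITGB4 (1.22 ± 0.08), the laminin gene LAMB3 (0.56 ± 0.07, but 0.08 in shCBX8-1) and KRT19 (1.99 ± 0.28, mostly from shCBX8-1) among them, and 2 fell, CLDN2 being the lower, against 11 and 4 adjusted over the list alone (list 0.15). Of 60 mesenchymal and matrix genes 8 rose, with FBLN1 (1.12 ± 0.10) and SERPINE2 (1.04 ± 0.09), and 12 fell, with PMEPA1 (-0.88 ± 0.07) and the fibronectin gene FN1 (-0.84 ± 0.07), against 12 and 15 adjusted over the list alone (list 0.337). Among 37 matrix proteases and inhibitors, 4 rose, with PLAU (0.80 ± 0.08) and TIMP2 (0.43 ± 0.07), and 4 fell, with MMP7 (-0.74 ± 0.07) and MMP24 (-0.53 ± 0.08), against 5 and 4 adjusted over the list alone (list 0.796).

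Of 61 interferon-stimulated genes 3 rose, OAS1 (0.81 ± 0.08), OAS3 (0.51 ± 0.08) and TRIM14 (0.35 ± 0.07), also 3 adjusted over the list alone (list adjusted p = 0.171). Of 42 NRF2 targets, 5 fell, led by the haem oxygenase gene HMOX1 (-1.17 ± 0.08) with ALDH3A1 (-0.56 ± 0.05) and ME1 (-0.48 ± 0.08), and OSGIN1 rose (0.39 ± 0.08), against 9 and 7 adjusted over the list alone (list 0.796). TM7SF2 fell (-0.66 ± 0.12) of 26 cholesterol biosynthesis genes, also 1 adjusted over the list alone (list 0.171). Of 40 glycolysis and hypoxia targets 3 rose, with the glucose transporter gene SLC2A1 (0.80 ± 0.06) and ADM (0.47 ± 0.07), and P4HA2 (-0.39 ± 0.07) and SLC2A3 (-0.41 ± 0.08) fell, against 8 and 4 adjusted over the list alone (list 0.278). Of 45 amino acid and unfolded protein stress genes, 3 rose, with ATF5 (0.70 ± 0.08) and STC2 (0.60 ± 0.08), and 4 fell, with NUPR1 (-1.34 ± 0.11) and PSPH (-0.49 ± 0.09), against 6 and 7 adjusted over the list alone (list 0.928). Of 39 TGF-beta and YAP targets 4 rose, with AXL (0.39 ± 0.06) and AMOTL1 (0.50 ± 0.09), and PMEPA1 and CCN2 (-0.66 ± 0.13, but 0.10 in shCBX8-1, adjusted p = 0.818) fell, against 5 and 9 adjusted over the list alone (list 0.337). Of 36 Notch and Wnt targets 3 rose, with NOTCH1 (0.66 ± 0.07) and LFNG (1.22 ± 0.15), and SFRP1 (-0.62 ± 0.09) and NKD2 (-1.21 ± 0.19) fell, against 3 and 4 adjusted over the list alone (list 0.593). NKD2 did not pass without repeated accessions (adjusted p = 0.0869).

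Of 22 alveolar and airway markers the mucins MUC5AC (0.55 ± 0.07) and MUC5B (1.25 ± 0.18) rose in the mean of both groups and TPPP3 fell (-0.49 ± 0.10), against 3 and 3 adjusted over the list alone (list adjusted p = 0.607). Both mucin genes rose in shCBX8-2 (2.38 and 2.56), whereas in shCBX8-1 MUC5AC fell (-1.28) and MUC5B did not pass (-0.05). COX7C rose (0.92 ± 0.07) of 51 nuclear genes of the respiratory chain, also 1 adjusted over the list alone (list 0.198). Of 35 immediate early and heat shock genes FOSL1 (0.89 ± 0.10), HSP90AA1 (0.24 ± 0.05) and BAG3 (0.42 ± 0.09) rose and IER3 fell, against 3 and 3 adjusted over the list alone (list 0.726). With edgeR, 0 of 78 cytosolic ribosomal protein genes and 0 of 26 replication-dependent histone genes passed, over all genes or adjusted over the list alone, against 1 and 0 at an unadjusted p under 0.05 and 0 and 0 with DESeq2 (lists 0.278 and 0.961). Markers of other cell types were not called as lists. CORO1A (1.15 ± 0.13) and CD68 (0.36 ± 0.07) rose of 11 leukocyte markers (list 0.726, 2 up and 2 down adjusted over the list alone). MMP2 rose (0.88 ± 0.18) and COL1A1 fell (-0.86 ± 0.15) of 12 fibroblast markers (list 0.371, 2 and 1 adjusted over the list alone). Of 12 markers of HEK293-type kidney and neuronal cells STMN3 (0.80 ± 0.09) and TUBB3 (0.53 ± 0.07) rose (list 0.337, also 2 adjusted over the list alone). With edgeR 0 of 5 endothelial markers passed, 1 fell adjusted over the list alone, 1 was higher and 1 lower at an unadjusted p under 0.05, and 1 was lower with DESeq2 (list 0.45). Median, mean and test differed in sign in 8 of the lists not called, those of Polycomb subunits, matrix proteases, NRF2, stress response, alveolar, immediate early, leukocyte and HEK293-type genes. Some of these lists passed in other settings. Without 1 library these were cytosolic ribosomal proteins (adjusted p = 0.0368 without control 1, 0.0096 without shCBX8-1 replicate 1 and 0.0139 without shCBX8-2 replicate 2) and the respiratory chain (0.0499 without shCBX8-1 replicate 1). Interferon-stimulated genes passed without shCBX8-1 replicate 2 (0.0324), and p53 targets (0.00676) and cholesterol biosynthesis (0.013) without shCBX8-2 replicate 2. With the abundance trend removed p53 targets (0.00216), NRF2 targets (0.0027), cholesterol biosynthesis (0.00705) and cytosolic ribosomal proteins (0.0306) were called lower, the last against their direction with 1 library left out. With GC and length trends removed p53 targets (0.0366) and cholesterol biosynthesis (0.0419) were called lower. With the abundance trend removed the calls of CBX2 (0.34, adjusted p = 0.072), TRIM14 (0.31, 0.0578), CCN2 (-0.63, 0.0525), TPPP3 (-0.46, 0.0536), PA2G4 (0.16, 0.0555), HSP90AA1 (0.14, 0.193) and BAG3 (0.34, 0.0683) ended, with the log2 fold changes given first. With replicate number as a block 16 calls of genes named for knockdown against control ended, with adjusted p of 0.0509 to 0.0901. They were those of CBX2, KRT4, GADD45A, TP53I3, TRIM14, TM7SF2, P4HA2, SLC2A3, PSPH, TPPP3, NOP56, TCOF1, PA2G4, HSP90AA1, CD68 and MMP2. Without a filter on low counts those of CBX2 (0.0514) and BAG3 (0.0512) ended.

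The sample titles give each knockdown group a number, and each was compared with the control separately. In shCBX8-1, KRT19, an epithelial keratin, rose from 0.383 ± 0.0343 to 4.04 ± 0.0972 CPM (SD, n = 2), a log2 fold change of 3.39 ± 0.32 (SE, adjusted p = 0.00789). It stood next to OLFML3 (3.23 ± 0.22) and ANPEP (3.17 ± 0.26). SERPINA3, which codes for a protease inhibitor of the acute phase, fell from 11 ± 2.02 to 0.984 ± 0.105 CPM (SD, n = 2), with a log2 fold change of -3.48 ± 0.21 (SE, adjusted p = 0.00327). The fibrinogen-like gene FGL1 (-3.06 ± 0.41), the kinase gene MAPK4 (-2.85 ± 0.22) and PIP (-2.74 ± 0.50, adjusted p = 0.0451) were lower too. FAM156A (4.98 ± 0.79) rose and ARPC4-TTLL3 was higher (adjusted p = 0.0299), from 4 counts in control to 4.52 ± 2.58 CPM (SD, n = 2). SGK3, a kinase gene, had no count in shCBX8-1 and was at least 152-fold higher in control, against a floor of 3 counts over the group (adjusted p = 0.0411). Each of these shares sequence with another gene, and the sums, chosen after the values were seen, were compared. FAM156A with FAM156B had 62.2 ± 3.33, 64.8 ± 2.34 and 63.6 ± 8.46 CPM in control, shCBX8-1 and shCBX8-2. ARPC4-TTLL3 with ARPC4 and TTLL3 had 153.0 ± 4.96, 160.5 ± 8.61 and 153.2 ± 15.3 CPM. SGK3 with C8orf44-SGK3 had 6.24 ± 0.512, 6.99 ± 0.757 and 5.63 ± 2.00 CPM (SD, n = 2). The SDs of the ARPC4-TTLL3 sum exceed the 4.52 CPM of that gene, so its sum cannot show whether the change was real. As sequence is shared, the change of each of these single genes is uncertain. SGK3 and PIP did not pass without repeated accessions (adjusted p = 0.0544 and 0.0506) or without a filter on low counts (0.0728 and 0.0598), nor did FAM156A (0.0532) and ARPC4-TTLL3 (0.0549) without that filter. With the replicate block FAM156A (0.0598), SGK3 (0.0754) and PIP (0.0561) did not pass, and SGK3 did not with the robust fit (0.123). In all 423 genes passed, 229 up and 194 down. Without control 1 the count was 7, and without control 2, shCBX8-1 replicate 1 or shCBX8-1 replicate 2 it was 0 in edgeR (1698, 1925 and 1962 at an unadjusted p under 0.05). It was 2319 and 2327 without shCBX8-2 replicate 1 or 2 and 1477 by DESeq2 with all libraries kept.

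Among the lists in shCBX8-1, genes of G2 and mitosis were higher, with 8 of 62 risen, 23 adjusted over the list alone and a median of 0.28 (adjusted p = 1.39e-16, and adjusted p = 0.121 with an estimated correlation). Interferon-stimulated genes were higher as a list (median 0.23, adjusted p = 8.64e-07, and adjusted p = 0.326 with an estimated correlation), and 5 of 61 rose, while 17 rose and 1 fell adjusted over the list alone. Those 5 were OAS1, an antiviral enzyme (0.66 ± 0.09), and TRIM14 (0.46 ± 0.08), with HLA-B (0.85 ± 0.08), B2M (0.38 ± 0.06) and PSMB9 (0.61 ± 0.11), genes of antigen presentation named after their values were seen. S phase genes had a median of 0.20 (adjusted p = 1.82e-06, and adjusted p = 0.326 with an estimated correlation). With edgeR 0 of 60 passed, over all genes or adjusted over the list alone, against 21 higher and 1 lower at an unadjusted p under 0.05 and 12 higher with DESeq2. The HEK293-type markers were higher (median 0.26, adjusted p = 0.000172, and adjusted p = 0.326 with an estimated correlation), with STMN3 (1.25 ± 0.10), TUBB3 (0.47 ± 0.08) and PAX2 (1.17 ± 0.19, named after its value was seen) risen of 12 and 5 adjusted over the list alone. Inflammatory and NF-kB genes were lower (median -0.37, adjusted p = 0.0162, and adjusted p = 0.326 with an estimated correlation), with 4 fallen and 2 risen of 44, 14 and 5 adjusted over the list alone. The CDK inhibitors were called higher (median 0.26, adjusted p = 0.0162, and adjusted p = 0.326 with an estimated correlation), with CDKN2C risen and 2 adjusted over the list alone. Cornified genes were called higher too (median 0.40 but mean -0.02, adjusted p = 0.0304, and adjusted p = 0.326 with an estimated correlation), with SCEL and KRT4 risen and 5 up and 2 down adjusted over the list alone. Both lists include a gene of the series title. The p53 targets were called higher (median 0.15, adjusted p = 0.0252, and adjusted p = 0.326 with an estimated correlation), with PLK2 risen (0.50 ± 0.07, named after its value was seen) and 1 adjusted over the list alone. So were ribosome biogenesis genes (median 0.10, adjusted p = 0.0235, and adjusted p = 0.6 with an estimated correlation), with DKC1 (0.46 ± 0.07) risen and 1 adjusted over the list alone. With the abundance trend removed the p53 targets (adjusted p = 0.11) and ribosome biogenesis genes (0.258) were not called. Of the 29 lists, camera called 9 in shCBX8-1 and fry only 2, whereas in shCBX8-2 camera called 12 and fry 15.

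In shCBX8-2, H19 rose by 4.05 ± 0.10 (SE, adjusted p = 4.63e-05), ANPEP by 3.57 ± 0.26, CCNA1 by 3.0 ± 0.23 and MUC16 by 2.88 ± 0.18. FAM156A, which shares sequence with FAM156B, stood at 4.49 ± 0.78 (adjusted p = 0.0149). PAK3, a kinase gene, had no count in shCBX8-2 and was at least 34.8-fold higher in control (adjusted p = 0.00383). The potassium channel gene KCNJ4 changed by -4.00 ± 0.49, the alkaline phosphatase gene ALPG by -3.85 ± 0.54, the calcium channel gene CACNA1H by -3.79 ± 0.20 and the adhesion gene SDK2 by -3.67 ± 0.72 (adjusted p = 0.0225). With only the libraries compared FAM156A (0.0587) and SDK2 (0.0513) did not pass. There, 2169 genes passed, 1032 up and 1137 down. The count was 179 without control 1, 139 without control 2, 960 and 967 without shCBX8-1 replicate 1 or 2, and 3497 and 5515 without shCBX8-2 replicate 1 or 2.

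Cell-division lists were higher in shCBX8-2, with 42 of 62 genes of G2 and mitosis risen, 50 adjusted over the list alone (median 0.55, adjusted p = 8.64e-33, and adjusted p = 0.0408 with an estimated correlation). There were 36 of 60 S phase genes risen, 50 adjusted over the list alone (median 0.49, adjusted p = 1.2e-23, and adjusted p = 0.135 with an estimated correlation). Of 24 cornified genes 5 rose, with KRT15 (2.04 ± 0.14) and SCEL of the title, and 8 adjusted over the list alone (median 0.99, adjusted p = 5.96e-06, and adjusted p = 0.135 with an estimated correlation). Of 37 p53 targets 10 fell, with GDF15 (-1.18 ± 0.09) and GADD45A (-0.74 ± 0.09), and 18 adjusted over the list alone (median -0.37, adjusted p = 5.72e-07, and adjusted p = 0.135 with an estimated correlation). Inflammatory and NF-kB genes were lower, with 14 fallen and 3 risen of 44, 18 and 3 adjusted over the list alone (median -0.63, adjusted p = 0.000132, and adjusted p = 0.148 with an estimated correlation). Of 26 cholesterol genes 9 fell, with TM7SF2 (-0.94 ± 0.14), and 11 adjusted over the list alone (median -0.30, adjusted p = 0.00144, and adjusted p = 0.298 with an estimated correlation). Of 44 epithelial genes 14 rose, with ITGB4 (1.62 ± 0.09) and LAMB3 (1.04 ± 0.08), and 3 fell, 18 and 5 adjusted over the list alone (median 0.29, adjusted p = 0.000317, and adjusted p = 0.391 with an estimated correlation). Of 37 ribosome biogenesis genes 8 rose, 13 adjusted over the list alone (median 0.20, adjusted p = 1.93e-05, and adjusted p = 0.305 with an estimated correlation). Of 51 nuclear respiratory chain genes 3 rose, COX7C among them (0.99 ± 0.08), and 3 adjusted over the list alone (median 0.13, adjusted p = 0.000811, and adjusted p = 0.656 with an estimated correlation). Called higher as well were the cytosolic ribosomal protein genes (median 0.09, adjusted p = 0.00357, and adjusted p = 0.778 with an estimated correlation), of which 0 of 78 passed with edgeR, over all genes or adjusted over the list alone, 9 were higher at an unadjusted p under 0.05 and 4 with DESeq2. Glycolysis and hypoxia targets were called higher against the sign of their median (-0.0041, mean 0.07), with 12 risen and 2 fallen of 40, 16 and 5 adjusted over the list alone (adjusted p = 0.0423, and adjusted p = 0.436 with an estimated correlation). So were alveolar and airway markers (median -0.013, mean -0.02), with 3 risen, MUC5AC and MUC5B among them, and 2 fallen of 22, 3 and 3 adjusted over the list alone (adjusted p = 0.0436, and adjusted p = 0.389 with an estimated correlation). With the abundance trend removed the ribosome biogenesis median was 0.09 (adjusted p = 0.0316), and the call of the cytosolic ribosomal protein genes ended with the opposite sign (median -0.07, adjusted p = 0.296). Those of the respiratory chain (median 0.04, adjusted p = 0.296) and of glycolysis (adjusted p = 0.512) ended too. With GC and length trends removed the cytosolic ribosomal protein (adjusted p = 0.107), glycolysis (0.0859) and alveolar (0.0779) lists were not called.

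The difference between the knockdown groups was tested directly. The airway mucin gene MUC5AC stood at 56.2 ± 3.55 CPM in control, 23.2 ± 0.866 in shCBX8-1 and 293 ± 4.6 in shCBX8-2 (SD, n = 2). The difference was 3.66 ± 0.09 log2 (SE, adjusted p = 2.93e-05), with opposite calls against control (-1.28 ± 0.08 and 2.38 ± 0.08). SERPINA3 (3.69 ± 0.21), MAPK4 (3.66 ± 0.23) and the elafin gene PI3 (2.80 ± 0.25) were higher in shCBX8-2, and NMUR2, a neuropeptide receptor gene (-4.19 ± 0.21), CEND1 (-4.01 ± 0.33) and INSYN2B (-3.96 ± 0.36) were lower. MAPK4, PI3, NMUR2, CEND1 and INSYN2B also had opposite calls against control. PAK3 was at least 143-fold higher in shCBX8-1, SGK3 at least 246-fold higher in shCBX8-2 and ARPC4-TTLL3 at least 190.0-fold higher in shCBX8-1. With the robust fit SGK3 did not pass here (adjusted p = 0.0587). The p53 targets had the smallest p of the 29 lists. Of 37, 17 were lower in shCBX8-2 and 20 did not pass, with 23 lower and 1 higher adjusted over the list alone (median -0.48, adjusted p = 4.11e-13, and adjusted p = 0.139 with an estimated correlation). In all 1681 genes differed, 693 higher and 988 lower in shCBX8-2. By camera 16 lists differed, 9 higher and 7 lower, of which 0 passed with an estimated correlation. By fry 19 of the 29 lists differed. The count of genes was 615 without control 1, 618 without control 2, 126 and 144 without shCBX8-1 replicate 1 or 2, and 2858 and 5104 without shCBX8-2 replicate 1 or 2.

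**Figure D3:**
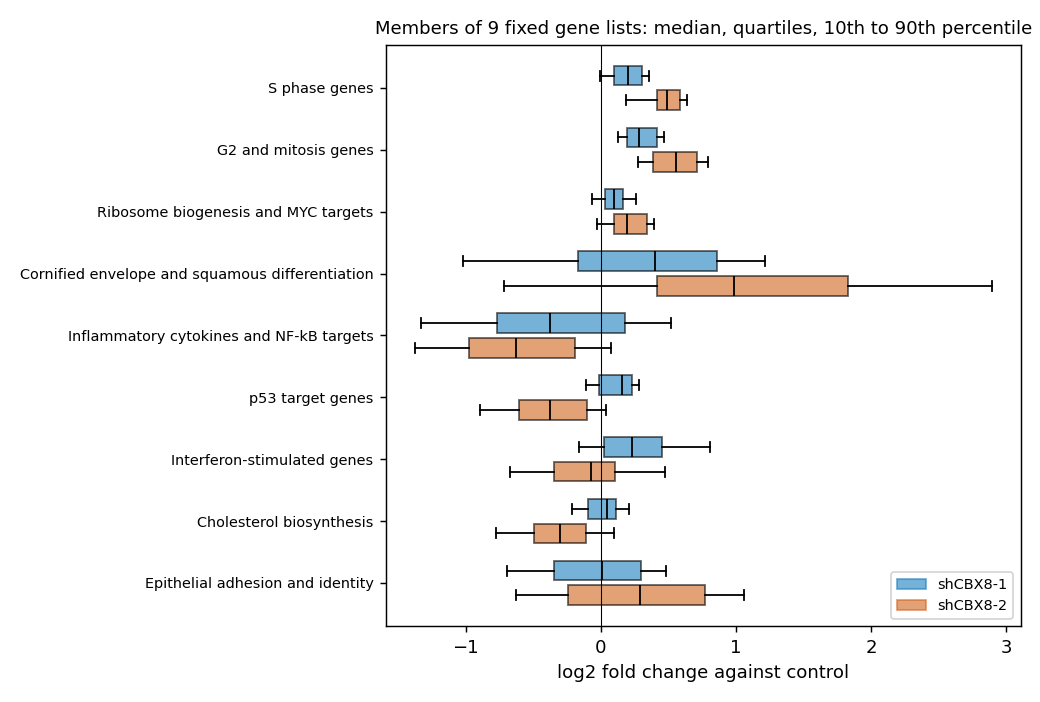
Log2 fold changes against control of the members of 9 fixed gene lists in shCBX8-1 (blue) and shCBX8-2 (orange), with median, quartiles and 10th to 90th percentile. The S phase medians are 0.20 and 0.49 and the p53 target medians 0.15 and -0.37.

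Genes changed in both knockdown groups were then counted. There were 132 higher in both, ANPEP, MUC16 and H19 among them, and 80 lower in both, with TM4SF20 and CLDN2, while 36 changed in opposite directions. Independent calls would share 13.8 and 12.9 genes. With both groups unchanged on shared controls, 50 simulations shared 0.2 genes on average and 2 at most, from at most 7 and 5 calls per group, so this value covers chance without any effect. The 212 genes made up 50.1% of the shCBX8-1 calls and 9.77% of the shCBX8-2 calls, and 994 of the shCBX8-2 calls also differed from shCBX8-1. Without control 1 the number in both was 2, and without control 2 or either shCBX8-1 library 0 in edgeR (1698, 1925 and 1962 genes at an unadjusted p under 0.05 in shCBX8-1). Without shCBX8-2 replicate 1 or 2 it was 1025 and 1127, against 716 with DESeq2 and all libraries. Across the 17115 genes the log2 fold changes of both groups had a Pearson r of 0.358. Without control 1 or 2 it was 0.56 and 0.552, and no r of unchanged groups on a lone control was simulated for these. Unchanged groups on the 2 shared controls gave a simulated mean r of 0.503, above the 0.358 observed. The share of genes with the same sign was 64.8% observed and 66.7% simulated on average, and the covariance was 0.334 observed and 0.145 simulated. Effects found in 1 group alone lower r and the same-sign share, so their shortfall cannot decide on agreement. Only the covariance exceeded the simulation, where it was 0.160 at most. On that measure the groups varied together more than unchanged groups did. All simulated groups had the same spread, unlike the real libraries, so the extent of agreement across all genes is not settled. Genes are not independent replicates and no p is given. The 2 controls were not split, since each part would hold a lone library, and part of the shared calls may come from the controls themselves.

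**Figure D4:**
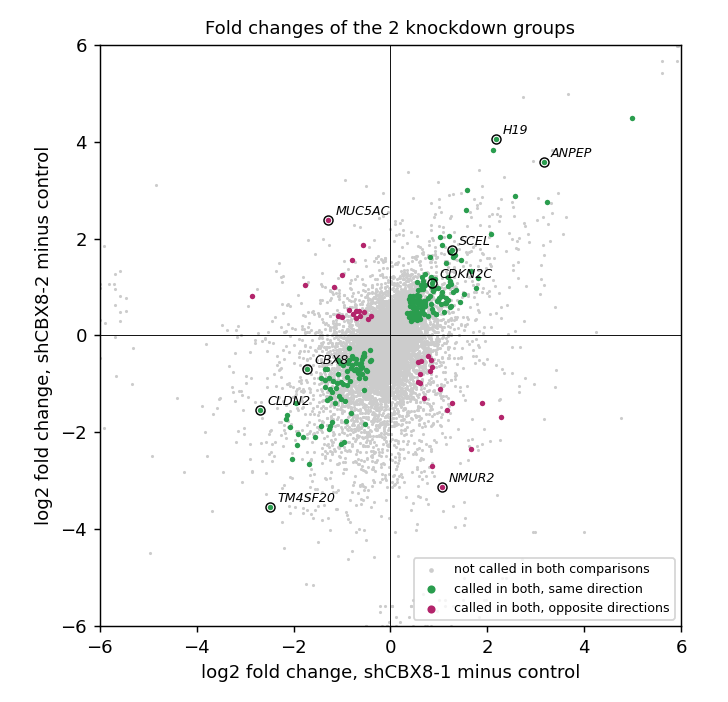
Log2 fold change against control in shCBX8-1 (horizontal) and shCBX8-2 (vertical) of 17115 genes, of which 276 lie outside the axes of 6 log2 each way. Genes called in both groups in the same direction are green (212) and in opposite directions magenta (36), with CBX8, CDKN2C and SCEL labelled.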

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

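The tests of shCBX8-2 against shCBX8-1 were planned. The removal of trends on abundance or GC content and length, and the rise from 100 to 10000 permutations in the last test, were chosen after the results were seen. All results in this part are listed because the effects of the 2 knockdown groups against control differed by that test. Of 119 genes named by the rule 65 differed, 38 higher and 27 lower in shCBX8-2, with adjusted p from 2.93e-05 to 0.0461. The rule took part of these genes for their change in this contrast or in 1 group, which raises that share. Over all genes 1681 of 17115 differed. Values are log2 fold changes of shCBX8-2 minus shCBX8-1. The number of all genes that differed, 1681, was 615 and 618 without control 1 or 2, 126 and 144 without shCBX8-1 replicate 1 or 2, and 2858 and 5104 without shCBX8-2 replicate 1 or 2. With both groups against control, 6 named genes passed in opposite directions, with differences of 3.66 for MUC5AC, 3.66 for MAPK4, 2.80 for PI3, -4.19 for NMUR2, -4.01 for CEND1 and -3.96 for INSYN2B. All 6 were among the genes taken for the widest differences between the groups, which favours opposite calls. Over all genes 36 passed in opposite directions and 212 in the same direction.

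CBX8 itself differed by 1.02, its relative CBX2 by 0.57, and the developmental regulators ZIC2, KLF4 and SOX2 by 0.52, 0.89 and -3.09. Among genes lower in both groups, TM4SF20 differed by -1.06, SLC7A7 by -0.98 and CLDN2 by 1.16. Among genes higher in both, H19 differed by 1.88, CCNA1 by 1.42 and MEGF6 by 1.01. Of the genes with the widest changes in a single group, SERPINA3 differed by 3.69, FGL1 by 1.83, PIP by 2.78, KRT19 by -2.80, KCNJ4 by -3.35 and CACNA1H by -2.90. ARPC4-TTLL3 was at least 190.0-fold higher in shCBX8-1, SGK3 at least 246-fold higher in shCBX8-2 and PAK3 at least 143-fold higher in shCBX8-1, and the reads of ARPC4-TTLL3 and SGK3 are shared with other genes.

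The cell-cycle genes FEN1 (0.40), RRM2 (1.45), MCM7 (0.41), MCM4 (0.39), MKI67 (0.41) and TUBB4B (0.36) were higher in shCBX8-2, as were NOP56 (0.31) and TCOF1 (0.42) of ribosome biogenesis. The p53 targets GDF15 (-1.06), GADD45A (-0.67) and TP53I3 (-0.40) were lower. Of epithelial and cornified genes, KRT15 (1.5), KRT16 (1.45), ITGB4 (0.80) and LAMB3 (0.96) were higher, whereas KRT19, given above, was lower. The mucin gene MUC5B was higher by 2.6 and TPPP3 by 0.73. Of matrix genes, PMEPA1 (1.25), FBLN1 (1.56) and MMP7 (0.90) were higher and FN1 (-0.58), PLAU (-0.62), MMP24 (-0.44), COL1A1 (-0.82) and CCN2 (-1.51) lower. Of stress and metabolic genes, ALDH3A1 (0.59), OSGIN1 (0.58), SLC2A1 (0.33), P4HA2 (0.55) and HSP90AA1 (0.30) were higher and HMOX1 (-1.31), ME1 (-0.61) and NUPR1 (-0.83) lower. LFNG differed by 0.70, SFRP1 by -0.44, MAP3K8 by -0.69, FOSL1 by -0.45, CD68 by -0.33 and STMN3 by -0.90.

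As lists, 16 differed, each with an adjusted p from 0.139 to 0.671 with an estimated correlation. Higher in shCBX8-2 by their medians were cornified genes (0.44), S phase genes (0.29, adjusted p = 2.68e-10), genes of G2 and mitosis (0.28, adjusted p = 1.08e-08), epithelial adhesion (0.29), glycolysis and hypoxia (0.05), alveolar and airway markers (0.0028), cytosolic ribosomal proteins (0.15), ribosome biogenesis (0.09) and the nuclear respiratory chain (0.23). Lower were HOX genes (-0.28), p53 targets (-0.48, adjusted p = 4.11e-13), mesenchymal genes (-0.37), interferon-stimulated genes (-0.27), cholesterol biosynthesis (-0.36), replication-dependent histones (-0.51) and HEK293-type markers (-0.57). With the abundance trend removed 5 of these lists were no longer called, cytosolic ribosomal proteins (median 0.04, adjusted p = 0.31), ribosome biogenesis (0.03, 0.242), glycolysis and hypoxia (0.01, 0.226), HOX genes (-0.22, 0.127) and histones (-0.36, 0.0757).

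The rise of S phase genes (adjusted p = 0.196 with an estimated correlation) and of G2 and mitosis genes (0.0407) in knockdown against control was weighed against trends between libraries. With each library's trend on abundance removed, the lower of both list medians was 0.314, and with trends on GC content and length removed it was 0.341, both above the 0.2 set beforehand, with both lists still called at the preset correlation. This argues against either trend as the whole cause. The medians of S phase and of G2 and mitosis genes were 0.20 and 0.28 in shCBX8-1 and 0.49 and 0.55 in shCBX8-2. CBX8 stood at 30.4% of control in shCBX8-1 and at 61.9% in shCBX8-2, so the rise was not larger where less CBX8 was left. A response to the knockdown remains open as a hypothesis, and so does a difference in the growth state of the cultures. The design cannot separate these and no test of them was run.

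With 1 shared estimate of the spread, more genes passed in shCBX8-2 than in shCBX8-1, 2169 against 423, a ratio of 5.13. The libraries of shCBX8-2 differed from each other by a median of 0.240 log2 per gene, against 0.128 in shCBX8-1. With each group fitted with the controls alone the order reversed, 995 against 2426, so the higher number in shCBX8-2 depends on the shared spread. In the fit to all 6 libraries with the abundance trend removed the ratio was 3.87, above the 2.5 set beforehand. This argues against that trend as the whole cause. The ratio was 2.6 with GC and length trends removed, where both counts rose, to 1371 and 3560. A GC or length trend stays open for part of the difference. By the DESeq2 Wald test the ratio was 2.41 and by the robust fit 4.03, neither of which removes such a trend. A single deviating shCBX8-2 library stays open, since the ratio was 1.51 without replicate 1 and 2.37 without replicate 2, and it was 0.41 when each group was fitted with the controls alone. For silencing through hairpin seed matches, the lowest z for shCBX8-2 among words of the CBX8 transcript was -3.98, against a highest z of 7.97 over all words. It was undercut in 8.97% of 10000 permutations (exact 95% interval 8.42 to 9.55%) and in 8.0% of 100. Both lie above the 5% set beforehand, which by that rule argues against such silencing as the whole cause. Its word, CCTCAAA, was however the lowest of all words. It was the lowest again in shCBX8-2 against shCBX8-1 (z = -4.28), undercut there in 2.0% of 100 permutations. The evidence is therefore mixed, and a share of such silencing and an untested difference in biology stay open.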

How the results depend on the processing

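Repeated accessions, the robust fit and the removal of trends were alternatives chosen after the data were seen. The results rest on the spread between libraries, to which the shCBX8-2 libraries add most, and leaving out a library leaves a lone sample assumed to vary like the others. With 1 library left out the number of genes changed ran from 1 to 4467 for knockdown against control, 0 to 2327 for shCBX8-1, 139 to 5515 for shCBX8-2, 126 to 5104 between the groups and 0 to 1127 in both, the CBX8 fold change from -1.29 to -1.12, the correlation from 0.331 to 0.56 and the lists called from 5 to 9. In the order knockdown, shCBX8-1, shCBX8-2, between groups and in both, counts were 261, 155, 623, 573 and 51 with a 2-fold minimum, 2441, 1477, 3560, 2958 and 716 with the DESeq2 Wald test, 2484, 1371, 3560, 3010 and 714 with GC and length trends removed, and 0, 0, 0, 1 and 0 for transcripts as deposited with edgeR (3505, 2788, 4048 and 3841 at an unadjusted p under 0.05 in the 4 contrasts), where more features are tested. With the replicate block, whose pairing is not borne out (deviations of libraries with the same number correlated by -0.017 to 0.016), the counts were 696, 173, 1684, 1082 and 84. The 4 knockdown libraries as 1 group gave 27 genes and a CBX8 fold change of -1.11 (adjusted p = 0.252), and transcripts as deposited gave -1.21 (0.26). With only the libraries compared, 2426 genes passed for shCBX8-1 and 995 for shCBX8-2, as the spread was then that of 2 groups. The correlation was 0.47 without a filter and 0.334 with the abundance trend removed. Camera with an estimated correlation called 1 list, fry 9, and camera with the abundance trend removed 10. DESeq2 size factors, no filter, no repeated accessions, the robust fit and the abundance trend kept all 5 counts of genes within 1.5 times. The 5 lists called for knockdown against control passed in all 13 settings tried of camera at the preset correlation, with medians of 0.38 to 0.47 for G2 and mitosis, 0.31 to 0.38 for S phase, 0.42 to 0.85 for cornified genes, 0.08 to 0.18 for ribosome biogenesis and -0.47 to -0.29 for NF-kB targets. Of 2077 alternative values of named genes 1487 kept their call, 590 lost it and 0 turned direction. Transcripts as deposited gave no value for genes with several transcripts. Where not said, the cause was not tested. Low counts limit genes near the floor of 3 counts over a group.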

Other observations

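The genes and tests of this and the next 2 paragraphs, and in the last the test of the base after a site, were chosen after the results were seen. HLA-B and PSMB9, members of the interferon list, changed in opposite directions in the knockdown groups. HLA-B rose by 0.85 ± 0.08 in shCBX8-1 and changed by -0.51 ± 0.08 in shCBX8-2, a difference of -1.35 ± 0.08 (SE, adjusted p = 0.000899). PSMB9, an immunoproteasome subunit, rose by 0.61 ± 0.11 and changed by -0.97 ± 0.11. TAP1, a peptide transporter subunit, and UBE2L6 were lower in shCBX8-2 than in control, by -0.67 ± 0.08 and -1.31 ± 0.13, whereas OAS1 was higher in both groups. B2M rose in shCBX8-1 (0.38 ± 0.06) and did not pass in shCBX8-2 (adjusted p = 0.996). No list of antigen presentation genes was tested. Among CDK inhibitors, CDKN1A, a p53 target, stood at 0.23 in shCBX8-1 (adjusted p = 0.155) and changed by -0.37 ± 0.07 in shCBX8-2 (adjusted p = 0.0183).

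The mucin genes MUC5AC and MUC5B rose in shCBX8-2, by 2.38 ± 0.08 and 2.56 ± 0.21, as did SPDEF, a transcription factor of mucus-secreting cells (0.74 ± 0.16, adjusted p = 0.0264). The lung transcription factor gene NKX2-1 changed there by -2.34 ± 0.59 (adjusted p = 0.0477). Genes of low mean level were lower in both groups, with medians of -0.17 in shCBX8-1 and -0.40 in shCBX8-2 below 1 CPM, and 0.05 and 0.12 at 100 CPM or more. In shCBX8-1 with the abundance trend removed, the p53 list had a median of 0.12 instead of 0.15 and was no longer called (adjusted p = 0.11), nor were the ribosome biogenesis genes (0.258).

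Of 11 genes with at least 1 CPM within 500 kb of CBX8, CBX2 (0.38 ± 0.09) and EIF4A3 (0.28 ± 0.06) rose in knockdown against control, and RBFOX3 (-1.82 ± 0.18) and SLC26A11 (-0.50 ± 0.10) fell. Among genes with at least 1 CPM, the median log2 fold change of each of 22 autosomes was set against that of all such genes. These deviations ran from -0.0619 to 0.0251 in shCBX8-1 and from -0.0753 to 0.0718 in shCBX8-2.

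Words of 7 bases in 3′ UTRs were searched in 12361 genes, since hairpins can act on other genes through their seed. Genes with GTGAGCT, a word also found in the CBX8 3′ UTR, were lower in shCBX8-1 (z = -7.10, against a lowest z of -5.10 over all words in 100 permutations). Genes with AAGAGCA were higher in both groups (z = 4.72 and 7.97, against highest permuted values of 5.15 and 5.35). Of genes called lower in shCBX8-1, 31.4% held GTGAGCT against 15.5% of others, and of genes called higher in both groups, 34.6% held AAGAGCA or GAAGAGC against 21.6%. As the words were picked from the same fold changes, these shares describe that choice and test nothing. For GTGAGCT in shCBX8-1 and AAGAGCA in both groups, Alu elements and a single deviating library were argued against as the whole cause. Their z stayed at least 4.28 in size among genes without 10 Alu words and at least 3.8 in size over all pairs of single libraries. Either as the cause would give less than 2. For GAAGAGC z was 4.03 in shCBX8-1 among genes without Alu words, and pairs of single libraries were not tested. Silencing through hairpin seeds is a candidate explanation that stays open as a hypothesis. Genes with an A after the GTGAGCT site, a mark of seed matches, were lower in shCBX8-1 than those with another base (one-sided permutation p = 0.0307). Of the 1946 genes with GTGAGCT, 849 held no Alu word, and this test was not run in those alone. A difference in Alu content between the compared genes therefore stays open for it. For GAAGAGC, genes with an A after the site were higher (permutation p = 0.0002). Followed by A it contains AAGAGCA, a word picked for its high z in these same fold changes, so this difference is no independent evidence. A control hairpin with that seed could give words higher in both groups, but hairpin sequences were not used here, and a seed of shCBX8-1 does not predict the z of 4.31 for GTGAGCT in shCBX8-2. CDKN2C and SCEL hold neither word. In knockdown against control the medians of S phase and of G2 and mitosis genes without any of these words were 0.34 and 0.42. Those of the 13 and 10 genes with a word were 0.32 and 0.56.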
